A study of Homo sapiens with 9 samples.

How the data were processed

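The data are poly(A) RNA sequencing of 9 libraries, 3 each of the untreated cell lines PEO1, PEO1-R and PEO4. Samples were grouped by the line named in their labels, and each library's column was matched by its title. All 9 libraries were used and no column of values was left unmatched.

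The authors deposited a table of counts per gene with a gene length column, from which counts were used as they stand. A table in FPKM, deposited by the authors for the same libraries with a mean per line, was used only for alternatives and checks. Per the submitters' processing notes the genome build was GRCh38 (hg38), and HISAT2 2.2.1 and STAR, without a version, were among the tools. Their roles, the counting program, its annotation and the strand setting were not given in the sources used here. For genes over 20 counts, the deposited FPKM was checked to equal the count divided by gene length and a library total, within a relative difference of 3.5e-08. That total was itself derived from the FPKM of these genes, as a median. Gene positions of all 58735 genes were checked against GENCODE 29 and matched. Among the gene symbols 1745 stood on more than 1 row, and genes were handled by identifier. All levels, positions and symbols are printed as in those tables.

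Counts assigned to genes ranged from 16957769 to 32867855 per library, and 22673 to 24156 genes had a count. At these depths 3 counts correspond to 0.0913 to 0.177 counts-per-million (CPM). Genes were kept by edgeR's filterByExpr with the 3 groups, which left 16642 tested and 42093 out. CPM values use TMM-scaled library sizes.

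Main tests, chosen before the data were examined, used R 4.3.3, edgeR 4.0.16 and limma 3.58.1. One fit of group means to all 9 libraries (glmQLFit with robust = TRUE, glmQLFTest) gave 6 residual degrees of freedom and a biological coefficient of variation of 20.2%. Each of 3 contrasts was adjusted by Benjamini-Hochberg over the tested genes, with an adjusted p threshold of 0.05. Errors of log2 changes (SE) were taken from the fitted change and its F statistic. For a gene with 0 counts in a line the fold is given as "at least", with the line set to 3 counts over its 3 libraries. With 1 to 3 counts the ratio is given with an exact Poisson 95% interval, and in neither case is the fitted fold printed.

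Of 37 gene lists, written before the data were examined, 36 had enough tested members for limma's camera on log2 CPM (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast). Camera compares a list with the other genes. The estimated correlation and fry, which asks whether a list moves on balance in a single direction rather than against other genes, were alternatives. Members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Of 950 list symbols 947 were matched. Camera was also run on bins of 10 Mb with at least 15 tested genes, 284 bins per contrast, with 100 shuffles of genes over bins. Genes expressed in a single line had at most 3 counts in the other and a mean of at least 5 CPM, and were counted without a test. Shared changes were set beside 20 simulations of unchanged groups against the same PEO1 libraries.

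Genes were named by a rule. Per contrast these were (a) the 6 protein-coding genes with the largest rise and the 6 with the largest fall past the threshold, at 10 CPM or more in the higher line. Next came (b) up to 4 members of each list with the smallest p per direction, (c) BRCA1, BRCA2, TP53, RAD51, TP53BP1, PARP1, PARG, SLFN11, ABCB1, POLQ, EZH2 and CCNE1 whatever their values, and (d) 5 genes higher and 5 lower in both resistant lines. The rest were (e) 2 genes of each described segment, the 4 segments with the smallest p per direction, and (f) up to 4 genes expressed in a single line of the pair. The text names a part of these, and genes outside the rule are said to be chosen after their values were seen. Of 319 genes so listed, 3 share more than 50% of their exon bases with another gene on the same strand (RAD51, RAD50, SRXN1) and 1 on the opposite strand (FTH1, with BEST1).

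Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors (upper quartile, DESeq2, library size alone, totals behind the FPKM), other filters, log2 FPKM with a pseudocount of 1 or 0.1, and the 6 libraries of each contrast alone. Further ones were a replicate block, an adjusted p of 0.01, a test against 1.5-fold (glmTreat), bins of 5 and 20 Mb, a 1 CPM minimum, and leaving out each library. After the data were seen, 3 were added: leaving out PEO1 replicate 3 and PEO1-R replicate 1, a term that marks these 2 libraries, and the totals behind the FPKM. A count within 1.5 times its main value was taken as the same, and a call lost or gained as weaker or stronger. A change of sign in an item past the threshold in neither setting was taken as the same and counted separately. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

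The steps were tested on simulated data with planted differences for PEO1-R against PEO1. Of 50 genes planted at each fold, 10% were recovered at 1.5-fold, 48% at 2-fold, 88% at 4-fold and 96% at 8-fold, and 15 of 136 calls were false (11.03%). A planted list of 30 genes at 1.5-fold had adjusted p = 1.95e-27 with 0 of 36 random lists called. A planted bin of 31 genes had adjusted p = 3.18e-22 with 0 of 283 other bins called. Genes were simulated independently of each other, so these list and bin runs do not test false calls where genes are correlated. Libraries were drawn independently too, so no run holds deviations shared between libraries.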

Results

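RNA sequencing was examined for 9 libraries of untreated human ovarian adenocarcinoma cells, 3 from each of the cell lines PEO1, PEO1-R and PEO4. A cell line is a population of tumour cells kept growing in culture, and the labels give all 3 lines as BRCA2 mutant and TP53 mutant. BRCA2 protein loads RAD51 onto broken DNA for repair by homologous recombination. Cells that lack this repair depend on poly(ADP-ribose) polymerase (PARP), and olaparib is a drug that blocks PARP. PEO1-R was selected from PEO1 over 6 months with 48-hour exposures to olaparib that rose from 0.5 to 20 µM. PEO4 is another established ovarian cancer line, commonly used beside PEO1 as resistant to platinum drugs and PARP inhibitors.

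Counts assigned to genes came to 32867855, 20319816 and 18177961 in PEO1 replicates 1, 2 and 3. They came to 20501101, 16957769 and 18685343 in PEO1-R and to 18619988, 17292557 and 18244857 in PEO4. Of 58735 genes, 16642 were tested. The p-values measure the spread between these libraries, which may be technical, since the labels do not say whether the replicates were separate cultures. Levels are counts-per-million (CPM), given as mean ± SD, and fold changes are fitted by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values.

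How the libraries lay towards each other was examined with principal components of log2 CPM. Component 1 (76.2% of variance) set PEO4, at 140 to 142, apart from the other 6 libraries, at -82.2 to -56.3. Component 2 (11.7%) set PEO1-R apart from PEO1. Component 3 (6.57%) set PEO1 replicate 3 (-42.0) and PEO1-R replicate 1 (-58.2) apart from the other PEO1 and PEO1-R libraries, at 14.9 to 33.3. These 2 libraries still correlated better with the rest of their own line than with the libraries of the other line that were not set apart. The means were 0.974 against 0.942 for PEO1 replicate 3 and 0.969 against 0.956 for PEO1-R replicate 1. With each other these 2 libraries correlated at 0.967. They are kept in the comparisons below, and main results are also given without them.

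**Figure D1:**
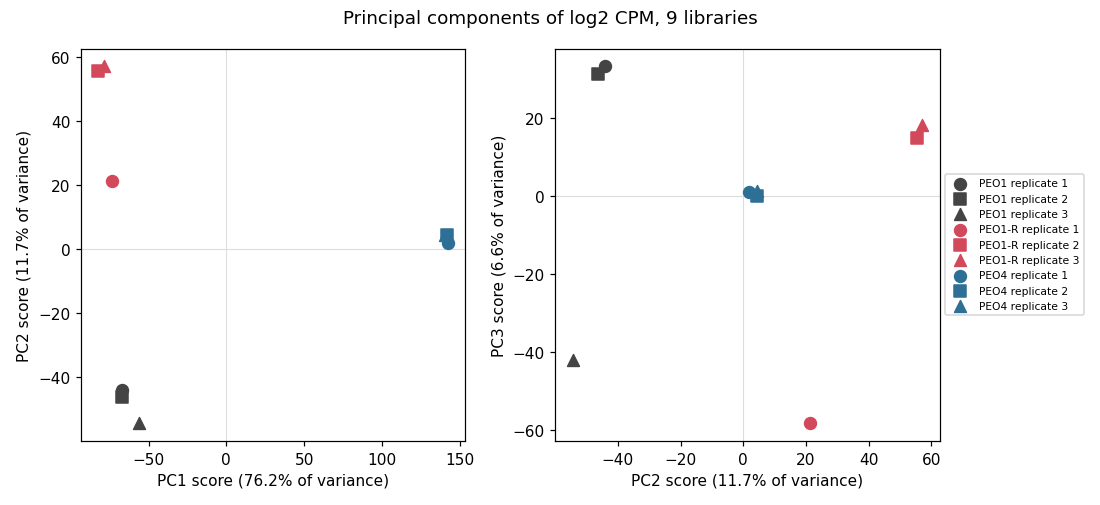
Principal components 1 to 3 of log2 CPM for the 9 libraries, coloured by cell line, with the percent of variance on each axis. Component 3 separates PEO1 replicate 3 and PEO1-R replicate 1 from the other libraries of their lines.

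Which genes differ after olaparib selection was asked by comparing PEO1-R with PEO1, with 3 libraries each. BRCA2 (chromosome 13:32315474-32400266, GRCh38) rose in PEO1-R, to 22.5 ± 1.34 CPM from 9.65 ± 0.448 CPM (SD, n = 3), a 2.33-fold difference (log2 1.22 ± 0.11 SE, adjusted p = 0.000217). VIM (10:17228259-17237593), which encodes the mesenchymal filament protein vimentin, rose 137-fold to 70.4 ± 1.58 CPM from 0.500 ± 0.0929 (SD, n = 3; adjusted p = 0.000254). ESR1 (6:151656691-152129619), the oestrogen receptor gene, fell 55.9-fold to 0.876 ± 0.434 CPM from 49.7 ± 1.99 (SD, n = 3; adjusted p = 4.45e-06). HOXB4 (17:48575513-48580111), a developmental transcription factor gene, had 0 counts in PEO1-R against 20.8 ± 6.17 CPM (SD, n = 3) in PEO1, at least 389-fold lower. Its neighbours HOXB3 and HOXB2 fell 50.5-fold (adjusted p = 3.02e-06) and 20.7-fold (adjusted p = 2.47e-05). In each of these genes, and in every gene named below as higher or lower at the threshold, all libraries of the 1 line lay on the same side of those of the other, which chance ordering gives in 10% of genes.

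In that comparison 1932 genes were higher and 2081 lower, 24.1% of those tested, and 851 and 619 of them differed at least 2-fold. Without PEO1 replicate 3 and PEO1-R replicate 1 the counts were 4860 higher and 4961 lower of 17053 genes, and 1903 and 2059 of the former calls were among them. That setting leaves 2 libraries each of PEO1 and PEO1-R, which correlated at 0.994 and 0.992. Its many calls follow the spread that was removed and are not stronger evidence. List members counted without the 2 libraries below are to be read against these totals. With the 6 libraries of PEO1-R and PEO1 alone, the counts were 1081 higher and 1087 lower. Leaving out PEO1-R replicate 1 alone gave 2815 higher and 3274 lower, while leaving out PEO1-R replicate 2 gave 1196 and 1261 and leaving out PEO1-R replicate 3 gave 1278 and 1325. Leaving out PEO1 replicate 1 gave 1146 higher, and leaving out PEO1 replicate 2 gave 1173 higher and 1370 lower. Of the genes called, 48.1% were higher with TMM scaling but 65.1% (2820 higher, 1512 lower) with library size alone, which shifted the median log2 change by 0.12. With fitted groups simulated as equal apart from planted genes, 88% of 4-fold and 48% of 2-fold differences were recovered. Of the calls 11.03% were false, above the share that the threshold of 0.05 aims at. The simulated libraries were drawn independently, without the shared deviations of PEO1 replicate 3 and PEO1-R replicate 1.

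Other large rises involved a claudin, a secreted protease and a cytokine. CLDN16 (3:190322541-190412143), a tight junction gene, rose 90.4-fold to 120 ± 52.2 CPM (SD, n = 3; adjusted p = 7.8e-05; log2 6.50, and 7.11 without PEO1 replicate 1). HTRA1, a secreted protease gene, rose 98.1-fold (log2 6.62, and 7.61 without PEO1 replicate 1; adjusted p = 4.39e-05), and RTL5, a retrotransposon-derived gene, rose 29.5-fold to 15.99 ± 4.64 CPM (SD, n = 3; adjusted p = 2.47e-05). IL1B, the gene of the inflammatory cytokine interleukin 1 beta, rose to 41.7, 6.81 and 8.91 CPM in PEO1-R replicates 1, 2 and 3 (log2 7.49, adjusted p = 0.0033), with log2 6.19 when replicate 1 was left out. GAGE2A, a germline antigen gene, stood at 10.8 ± 2.40 CPM (SD, n = 3) with 0 counts in PEO1, at least 246-fold higher. GAGE genes have near-identical copies, so which copy was counted is uncertain. Among the largest falls, the keratin gene KRT13 fell 53.7-fold from 15.8 ± 1.76 CPM (SD, n = 3; adjusted p = 3.02e-06). The cytokine signalling inhibitor CISH fell 23-fold (log2 -4.52, and -3.85 without PEO1 replicate 3; adjusted p = 0.000289).

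Epithelial and mesenchymal genes moved apart in PEO1-R. Of 28 tested mesenchymal genes 16 rose and 0 fell (18 and 2 adjusted over the list alone), with a median log2 change of 1.43 (camera adjusted p = 0.000188, but adjusted p = 0.752 with an estimated correlation). ITGA5, a fibronectin receptor gene, rose 2.8-fold (adjusted p = 0.000108). ZEB1 and ZEB2, repressors of epithelial genes chosen after their values were seen, rose 7.07-fold to 6.73 ± 1.55 CPM and 16.7-fold to 6.12 ± 1.67 CPM (SD, n = 3; adjusted p = 0.00914 and 0.000852). Of 30 epithelial genes 17 fell and 2 rose (18 and 2 adjusted over the list alone), with a median log2 change of -0.60 (camera adjusted p = 2.02e-05, but adjusted p = 0.752 with an estimated correlation). OVOL1 and GRHL1, transcription factors that maintain epithelial state, fell 16.2-fold to 1.65 ± 0.681 CPM (SD, n = 3; adjusted p = 0.000127) and 4.01-fold (adjusted p = 6.31e-05). ELF3 and CDH1, also chosen after their values were seen, fell 4.33-fold and 1.41-fold (adjusted p = 0.00167 and 0.00332), while MUC1 and LAMB3 rose 2.68-fold and 2.09-fold. CDH1, the gene of the junction protein E-cadherin, still stood at 125 ± 8.50 CPM (SD, n = 3). Without the 2 separated libraries the adjusted p-values were 0.00706 for the mesenchymal list (16 higher, 3 lower of 30) and 2.95e-06 for the epithelial list (4 higher, 22 lower).

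**Figure D2:**
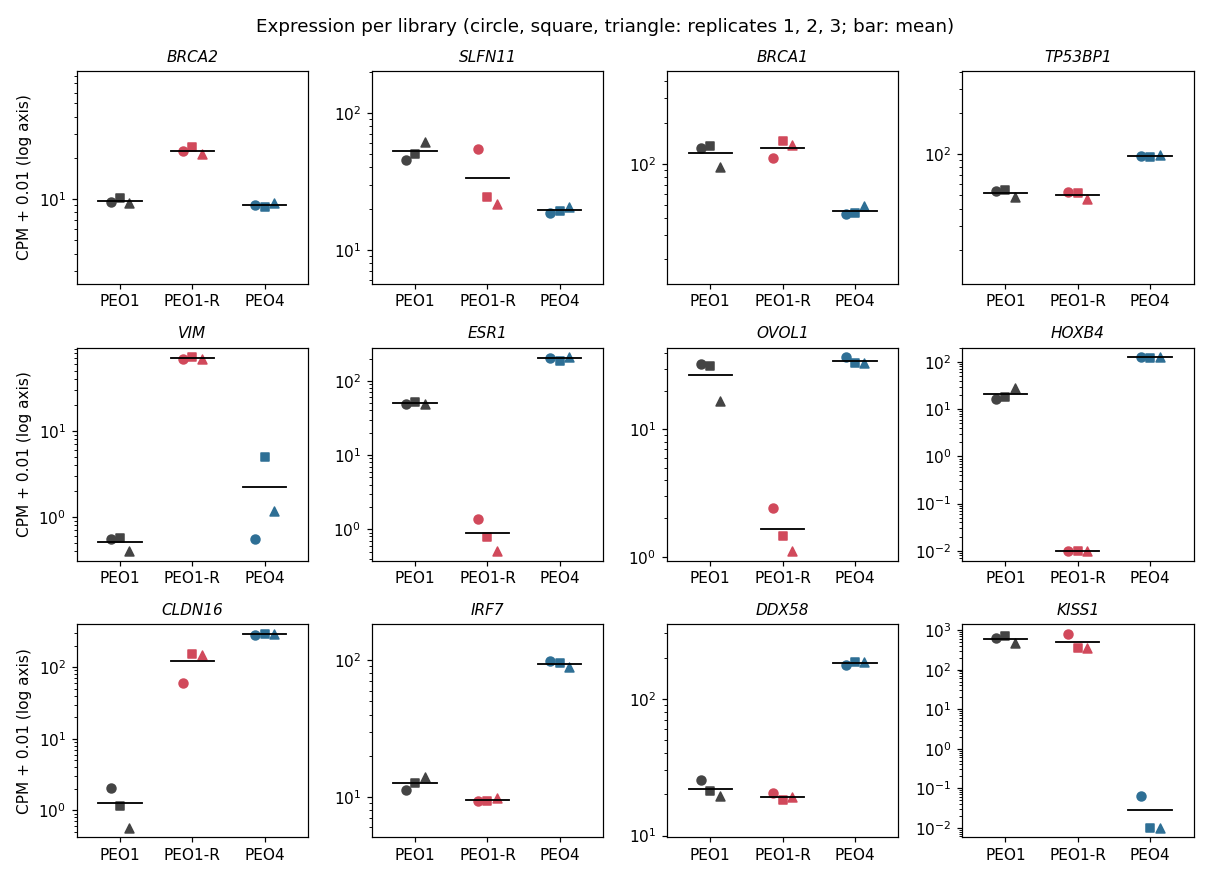
Levels of 12 genes in the 9 libraries, in CPM with 0.01 added on a log axis. Circles, squares and triangles are replicates 1, 2 and 3 of each line and bars are means.

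Genes tied to PARP inhibitor response were read in PEO1-R whatever their values. BRCA1 (log2 0.13, adjusted p = 0.575), TP53BP1 (log2 -0.04, adjusted p = 0.754), PARP1 (log2 0.01, adjusted p = 0.943) and PARG (log2 0.02, adjusted p = 0.872) were not past the threshold. Neither were POLQ (log2 0.31, adjusted p = 0.167), EZH2 (log2 -0.19, adjusted p = 0.124) and CCNE1 (log2 -0.02, adjusted p = 0.951). PARP1 encodes the target of olaparib, PARG removes poly(ADP-ribose), and TP53BP1 limits DNA end resection. SLFN11 (17:35350305-35373701), whose product blocks stressed replication forks, stood at 33.4 ± 18.3 CPM against 52.6 ± 8.24 (SD, n = 3; log2 -0.65, adjusted p = 0.16). Its counts in PEO1-R were 1130, 437 and 430, and without replicate 1 the change was log2 -1.21 with adjusted p = 0.000419. TP53 likewise moved from log2 0.25 (adjusted p = 0.207) to log2 0.42 (adjusted p = 0.00471) without PEO1 replicate 3. ABCB1, a drug efflux gene, had 0 counts in PEO1 and PEO1-R and was not tested. RAD51 had 8, 3 and 3 counts in PEO1 and 2, 3 and 1 in PEO1-R, and it was not tested. Because 71.5% of its exon bases are shared with another gene on the same strand, its reads may have been left unassigned.

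DNA repair lists were not past the threshold against other genes in PEO1-R. Of 34 homologous recombination genes 6 rose and 2 fell, the same as adjusted over the list alone (median log2 0.11, camera adjusted p = 0.312). RAD51D rose 1.8-fold (adjusted p = 0.00755), while RAD50 was 1.97-fold lower with most of its exon bases shared with another gene. In end joining and 53BP1-shieldin 3 of 20 rose and 0 fell, among them XRCC6 (1.61-fold) and STN1 (1.94-fold), with adjusted p = 0.609 for the list (8 higher and 5 lower without the 2 separated libraries). In single-strand break and base excision repair 2 of 28 rose and 5 fell, with APLF 2.46-fold higher and FEN1 1.64-fold and LIG1 1.57-fold lower (list adjusted p = 0.651; 13 higher and 8 lower without the 2 libraries). The Fanconi list (22 tested) had 2 higher and 3 lower, among them CENPX, 1.95-fold lower (list adjusted p = 0.959; 8 higher and 6 lower without the 2 libraries). Replication fork genes (26 tested) had 1 higher, TIMELESS (1.36-fold), and 2 lower (1 adjusted over the list alone), among them BOD1L1 (2.08-fold; list adjusted p = 0.868). Checkpoint genes of the ATR pathway (18 tested) had 1 higher and 5 lower, among them CHEK1, 1.32-fold lower (list adjusted p = 0.181), and by fry, which does not compare with other genes, the list was lower with adjusted p = 0.00613. Drug efflux genes (11 tested) had 2 higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.817), with ABCA3 1.46-fold higher and RALBP1 1.52-fold lower. Without the 2 libraries the homologous recombination list had 12 higher and 6 lower, the fork list 5 and 10, the checkpoint list 2 and 11 and the efflux list 4 and 4.

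Proliferation and lineage lists were not past the threshold in PEO1-R with all libraries. Mitotic genes (31 tested) had 8 higher and 3 lower, with TOP2A 1.46-fold higher and KIF20A 2.29-fold lower (median log2 0.20, adjusted p = 0.144, but 0.00346 without the 2 separated libraries, with 20 higher and 3 lower, and 0.00647 without PEO1 replicate 3 alone). Replication genes (36 tested) had 4 higher and 5 lower, with RRM1 1.31-fold higher and SLBP 2.89-fold lower (median log2 -0.18, adjusted p = 0.242, but 0.0381 without the 2 libraries, with 8 higher and 19 lower, and 0.0183 without PEO1-R replicate 1 alone). Ovarian lineage genes (18 tested) had 4 higher and 7 lower (4 and 9 adjusted over the list alone; median log2 -0.71, adjusted p = 0.103, but 0.0377 without PEO1-R replicate 1 and 0.0287 with library size scaling). KLK6, a serous carcinoma protease gene, fell 4.52-fold, and MECOM rose 4.33-fold. HOX genes (22 tested) had 1 higher and 6 lower (3 and 7 adjusted over the list alone; median log2 -0.08, adjusted p = 0.104, but 0.0404 without PEO1-R replicate 3 and 0.0356 with library size scaling). Stem-cell genes (17 tested) had 2 higher, CD44 (1.62-fold) and NES (12.2-fold), and 2 lower, among them ALDH3A1, at least 12.6-fold (list adjusted p = 0.823). Without the 2 libraries the ovarian lineage list had 4 higher and 10 lower, the HOX list 4 and 7 of 23 and the stem-cell list 5 and 6. By fry the ovarian lineage and HOX lists were lower, with adjusted p = 0.0212 and 0.00123. Of the cancer-testis list only PRAME was tested, and it was not past the threshold (log2 -0.74, adjusted p = 0.241).

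Inflammatory and stress lists of PEO1-R held members in both directions. NF-kB targets (24 tested) had 5 higher and 2 lower (median log2 0.15, adjusted p = 0.763), but 9 higher and 14 lower without the 2 separated libraries, with IL1A 13.1-fold and SOD2 2.56-fold higher and LCN2 2.6-fold lower. Interferon-stimulated genes (41 tested) had 6 higher and 6 lower (7 and 6 adjusted over the list alone; adjusted p = 0.866), with HERC5 2.4-fold higher and OASL 3.42-fold and ISG15 2.74-fold lower. Antigen presentation genes (20 tested) had 2 higher, HLA-A (2.36-fold) and NLRC5 (2.53-fold), and 4 lower, among them CD74 (6.83-fold; list adjusted p = 0.651). Apoptosis genes (26 tested) had 2 higher and 7 lower (2 and 8 adjusted over the list alone; adjusted p = 0.276, but 0.0179 by fry), with BIK 2.48-fold higher and BID 2.63-fold and the death receptor gene TNFRSF10B 1.8-fold lower. Targets of p53 (25 tested) had 5 higher and 5 lower (5 and 7 adjusted over the list alone; adjusted p = 0.868), with BBC3 2.4-fold lower. Unfolded protein response genes (30 tested) had 1 higher and 7 lower (1 and 8 adjusted over the list alone; adjusted p = 0.144, but 0.0371 without PEO1 replicate 3, 0.0409 without PEO1-R replicate 2 and 0.0417 without PEO1-R replicate 3), with the amino acid transporter genes SLC7A5 and SLC3A2 2.73-fold and 2.63-fold lower. NRF2 targets (22 tested) had 2 higher, among them UGDH (2.65-fold), and 4 lower, among them NQO1 (1.89-fold; list adjusted p = 0.817). Without the 2 libraries the interferon list had 10 higher and 16 lower, antigen presentation 7 and 10, apoptosis 7 and 11, p53 targets 9 and 11, the unfolded protein response 8 and 13 and NRF2 targets 7 and 10.

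Signalling and metabolic lists were also not past the threshold in PEO1-R. TGF-beta and BMP targets (22 tested) had 0 higher and 5 lower (4 adjusted over the list alone; adjusted p = 0.278, and 0.0381 without the 2 separated libraries), with BAMBI 4.9-fold and PMEPA1 1.72-fold lower. WNT genes (20 tested) had 3 higher and 5 lower (4 and 7 adjusted over the list alone; adjusted p = 0.559), with DKK3 4.73-fold higher and WNT5A 4.76-fold lower. Receptor kinase and PI3K-MAPK signalling genes (36 tested) had 4 higher, among them FGFR1 (2.27-fold) and FGFR4 (3.03-fold), and 2 lower, among them FGFR3 (4.88-fold; list adjusted p = 0.809), but 8 higher and 17 lower without the 2 libraries. Hypoxia genes (26 tested) had 1 higher and 3 lower (1 and 2 adjusted over the list alone), among them VEGFA, 1.94-fold lower (adjusted p = 0.306, but 0.026 without the 2 libraries and 0.0371 without PEO1 replicate 3 alone). Fatty acid genes (22 tested) had 5 higher and 2 lower (5 and 3 adjusted over the list alone; adjusted p = 0.736), but 7 higher and 12 lower without the 2 libraries, with ACSL4 1.55-fold higher and FASN 1.82-fold lower. Cholesterol genes (24 tested) had 1 higher, LSS (1.44-fold), and 1 lower (1 and 0 adjusted over the list alone; adjusted p = 0.731). Oxidative phosphorylation genes (39 tested) had 3 higher, among them NDUFB5 (1.28-fold), and 3 lower (3 and 2 adjusted over the list alone; adjusted p = 0.881). TGF-beta targets without the 2 libraries had 4 higher and 14 lower of 23, WNT genes 5 and 10, hypoxia genes 2 and 17 of 27, cholesterol genes 3 and 9 and oxidative phosphorylation genes 10 and 15.

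Lists of RNA quality, handling and other cell types were read beside these. Mitochondrially encoded mRNAs had 7 of 13 lower in PEO1-R and 0 higher (MT-CO2 1.97-fold, MT-ND2 1.82-fold; median log2 -0.80, adjusted p = 0.0354), and the adjusted p was 0.894 with an estimated correlation, 0.0543 without PEO1 replicate 1, 0.167 without PEO1 replicate 3, 0.061 without PEO1-R replicate 2 and 0.178 by fry. Immediate early genes had 5 of 16 lower and 0 higher (NR4A1 2.19-fold, DNAJB1 2.24-fold; median log2 -1.09, adjusted p = 0.00386, but adjusted p = 0.894 with an estimated correlation), and 15 lower and 0 higher without the 2 separated libraries. By fry this list also lost its call (adjusted p = 0.178), while the histone list kept it (0.00998). Histone genes had 2 of 21 higher and 0 lower (0 and 0 adjusted over the list alone; median log2 0.67, adjusted p = 0.0354, but adjusted p = 0.752 with an estimated correlation). The histone list had adjusted p = 0.136 without PEO1-R replicate 1 and 0.0604 with library size scaling. Fibroblast markers (8 tested) had 2 higher, among them the complement gene C1S (13.3-fold), and 0 lower (3 and 0 adjusted over the list alone; median log2 2.204, or 1.66 with the floor for 2 of them; adjusted p = 0.103, but 0.0371 without PEO1 replicate 3 and 0.0123 without PEO1-R replicate 2). Endothelial markers (8 tested) had 2 higher, among them KDR (26.2-fold, log2 4.71, and 6.62 without PEO1 replicate 3), and 0 lower (adjusted p = 0.731). Mesothelial markers (9 tested) had 1 higher, PDPN (3.89-fold), and 2 lower (1 and 3 adjusted over the list alone), among them KRT5 (8.12-fold; list adjusted p = 0.659). Neuronal markers (7 tested) had 2 higher, among them NCAM1 (3.71-fold), and 1 lower (2 and 2 adjusted over the list alone; adjusted p = 0.731). Leukocyte markers (3 tested) had 0 higher and 0 lower, with CSF1R at log2 1.15 (adjusted p = 0.208). Mitochondrial mRNAs without the 2 libraries had 6 lower and 0 higher (adjusted p = 0.102), and histone genes 8 higher and 0 lower of 22 (adjusted p = 0.148), and with a term for the 2 libraries both had adjusted p = 0.0696. Fibroblast markers without the 2 libraries had 5 higher and 0 lower of 10, endothelial 3 and 1, mesothelial 3 and 4, neuronal 3 and 1 and leukocyte markers 0 and 0. No list called in PEO1-R held its call with an estimated correlation.

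Neighbouring genes were compared in bins of 10 Mb to ask whether whole chromosome segments differ between PEO1-R and PEO1. Of 284 bins, 32 were higher and 34 lower, and 27 of them held with an estimated correlation. List members that lie in called bins were kept in the gene list tests, so a gene named from a list may have moved with its segment. The start of chromosome 4 fell as a block: 106 genes at 0 to 10 Mb had a median log2 change of -1.03 (93.4% of genes lower, adjusted p = 3.85e-22, and 0.00317 with an estimated correlation). MFSD10 and STX18 there fell 3.24-fold and 2.72-fold. The next bin, at 10 to 20 Mb, also fell (23 genes, median log2 -0.99, adjusted p = 4.39e-09), with LAP3 2.17-fold lower. Further along chromosome 4 the genes rose, with a median log2 change of 1.30 at 30 to 40 Mb (22 genes, adjusted p = 5.07e-08) and 0.90 at 40 to 50 Mb (31 genes, adjusted p = 2.45e-08). RFC1, a clamp loader gene, and RPL9 rose 2.62-fold and 3.08-fold in the former, and SLC30A9 rose 2.59-fold in the latter. Genes at 130 to 140 Mb of chromosome 5 fell (79 genes, median log2 -0.86, adjusted p = 6.06e-11), with FNIP1 3.27-fold and JADE2 2.08-fold lower. Genes at 70 to 80 Mb of chromosome 17 fell too (119 genes, median log2 -0.46, adjusted p = 9.08e-09), with CBX4 2.1-fold lower.

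Other segments of PEO1-R were less certain. The bin at 20 to 30 Mb of chromosome 19, rich in zinc finger genes, rose with a median log2 change of 0.57 (58 genes, adjusted p = 3.41e-08, but adjusted p = 0.109 with an estimated correlation), and ZNF431 there rose 1.78-fold. The bin at 100 to 110 Mb of chromosome X rose with a median log2 change of 0.44 (69 genes, adjusted p = 7.4e-06, but adjusted p = 0.0978 with an estimated correlation), with ARMCX4 2.36-fold higher. The bin that holds BRCA2, at 30 to 40 Mb of chromosome 13, was not past the threshold (34 genes, median log2 0.17, adjusted p = 0.12), so BRCA2 rose more than the median of its neighbours.

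**Figure D3:**
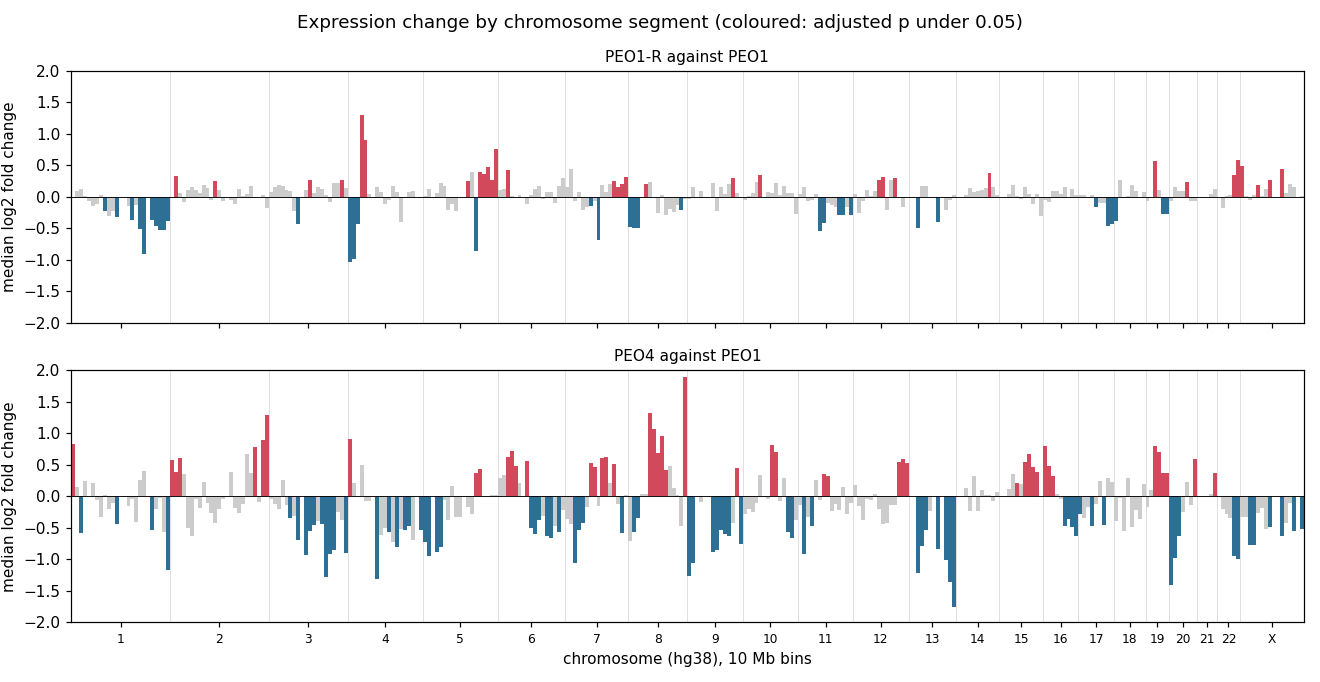
Median log2 fold change of tested genes in bins of 10 Mb along the chromosomes, for PEO1-R and PEO4 against PEO1. Coloured bins have a camera adjusted p under 0.05.

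What sets the resistant line PEO4 apart from PEO1 was asked with 3 libraries of each. Interferon-stimulated genes rose nearly throughout in PEO4, with 38 of 41 tested higher and 0 lower, the same as adjusted over the list alone (median log2 3.28, camera adjusted p = 1.03e-14, but adjusted p = 0.345 with an estimated correlation). DDX58, which encodes the RNA sensor RIG-I, rose 8.28-fold to 182 ± 4.55 CPM from 21.96 ± 2.98 (SD, n = 3; adjusted p = 1.5e-07). IRF7, an interferon regulator gene, rose 7.45-fold to 94.2 ± 5.03 CPM from 12.7 ± 1.44 (SD, n = 3; adjusted p = 1.72e-07). ISG15, IFIT1 and STAT1, chosen after their values were seen, rose 29.4-fold to 830 ± 26.9 CPM, 47.1-fold to 197 ± 5.99 CPM and 4.8-fold to 612 ± 6.59 CPM (SD, n = 3; adjusted p = 2.63e-06, 1.33e-06 and 8.08e-06). BRCA2 did not differ (9.05 ± 0.346 CPM, SD, n = 3; log2 -0.09, adjusted p = 0.504), whereas BRCA1 (17:43044295-43170245) fell 2.65-fold to 45.2 ± 3.13 CPM from 120 ± 21.7 (SD, n = 3; adjusted p = 6.01e-05).

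In PEO4 4895 genes were higher and 5168 lower than in PEO1, 60.5% of those tested, and 2861 and 2804 of them differed at least 2-fold. Without PEO1 replicate 3 and PEO1-R replicate 1 the counts were 6634 and 6733. With so many genes different, TMM scaling assumes that rises and falls balance, and 48.6% of called genes were higher, against 50.4% with library size alone.

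Some genes silent in PEO1 were expressed in PEO4. EMX2, a transcription factor gene of the urogenital tract, stood at 133 ± 8.49 CPM in PEO4 (SD, n = 3) with 0 counts in PEO1, at least 3030-fold higher, and its antisense gene EMX2OS was at least 6370-fold higher. NLRP2 (73.1 ± 3.57 CPM), MYL9 (49.3 ± 3.38 CPM) and HPN (53.4 ± 3.29 CPM, SD, n = 3) also had 0 counts in PEO1, at least 1670-fold, 1130-fold and 1220-fold higher. KISS1, a metastasis suppressor gene, ran the other way, with 604 ± 117 CPM (SD, n = 3) in PEO1 against 1 count in PEO4, a ratio of 32900 (95% counting interval 5900 to 1300000). The imprinted gene PEG3 had a ratio of 2570 (460 to 101000) in favour of PEO1, and RASGRF1 was at least 275-fold lower in PEO4. In all, 93 genes were expressed at 5 CPM or more in PEO4 with at most 3 counts in PEO1, and 19 genes the reverse. Leaving out PEO4 replicate 3 raised the 19 to 32. Such floors and intervals cover counting error alone, since counts were summed over the 3 libraries of a line and the spread between libraries was left out. The libraries also carry no molecular identifiers. In PEO1-R against PEO1 the same rule gave 1 gene, GAGE2A, expressed in PEO1-R alone, and 4 in PEO1 alone, among them HOXB4 and BEX1 (at least 122-fold). Leaving out PEO1 replicate 1 raised the 1 to 3, and leaving out PEO1-R replicate 1 or 2 raised it to 2.

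**Figure D4:**
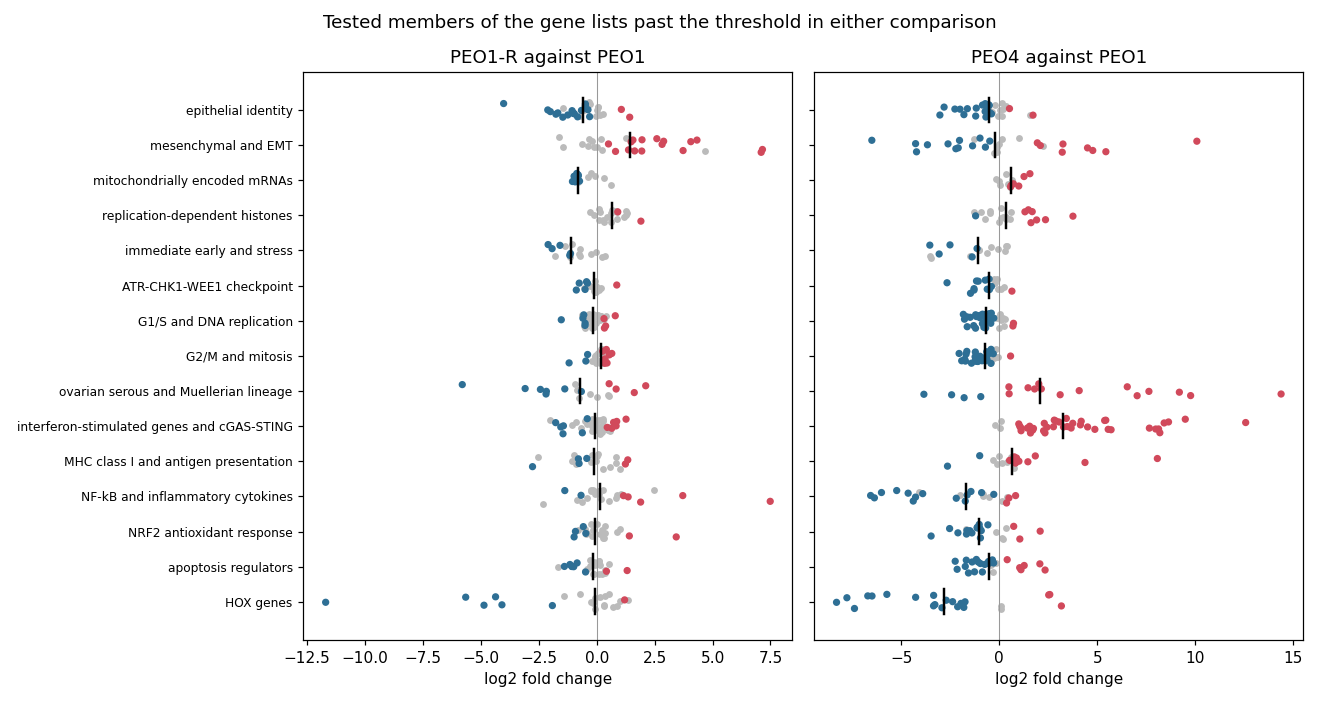
Log2 fold changes of the tested genes of 15 lists in PEO1-R and PEO4 against PEO1. Red and blue dots are genes higher and lower at an adjusted p under 0.05, grey dots are not past it, and black bars are medians.

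Ovarian lineage genes rose in PEO4, with 14 of 18 higher and 4 lower (median log2 2.08, adjusted p = 0.00228, but adjusted p = 0.622 with an estimated correlation). KLK7, a serous carcinoma protease gene, rose 584-fold to 348 ± 3.43 CPM (SD, n = 3; adjusted p = 6.89e-09), and CRABP2 rose 131-fold to 344 ± 7.55 CPM (SD, n = 3; adjusted p = 6.33e-07). PAX8 and ESR1, chosen after their values were seen, rose 4.42-fold to 439 ± 4.81 CPM and 4.05-fold to 201 ± 11.1 CPM (SD, n = 3; adjusted p = 1.66e-06 and 1.39e-05). HOX genes had 17 of 22 lower and 3 higher (median log2 -2.82, or -2.87 with the floor; adjusted p = 0.00261, but adjusted p = 0.572 with an estimated correlation). HOXD8 fell 105-fold (log2 -6.71, and -7.35 without PEO4 replicate 2) and HOXC9 had a ratio of 194 (53.6 to 1610) in favour of PEO1. HOXB2 and HOXB3 rose 5.75-fold and 9-fold, as did HOXB4, chosen after its values were seen (5.97-fold to 124 ± 1.39 CPM, SD, n = 3). In the cancer-testis list PRAME fell 12.3-fold (log2 -3.62, and -4.32 without PEO4 replicate 3; adjusted p = 0.00033).

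Cell cycle genes fell in PEO4. In the mitotic list 24 of 31 were lower and 1 higher (25 and 1 adjusted over the list alone; median log2 -0.75, adjusted p = 5.37e-06, but adjusted p = 0.622 with an estimated correlation). FOXM1, a mitotic transcription factor gene, fell 3.31-fold to 129 ± 3.34 CPM from 428 ± 10.3 (SD, n = 3; adjusted p = 4.82e-07), and ANLN fell 3.15-fold. In the replication list 26 of 36 were lower and 2 higher (median log2 -0.68, adjusted p = 0.000829, but adjusted p = 0.622 with an estimated correlation), with PCNA 3.56-fold and RRM2 3.14-fold lower and MCM3 1.62-fold higher. CCNE1, the cyclin E gene, fell 2.31-fold (adjusted p = 7.3e-05). In the ATR checkpoint list 11 of 18 were lower and 1 higher (median log2 -0.51, adjusted p = 0.0204, but adjusted p = 0.345 with an estimated correlation), with CDC25B 6.34-fold and RAD1 2.77-fold lower. With the 2 separated libraries left out, the mitotic list had 1 higher and 26 lower, the replication list 5 and 27 and the checkpoint list 2 and 13.

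Repair genes of PEO4 moved in both directions. Homologous recombination genes (34 tested) had 7 higher and 14 lower (8 and 14 adjusted over the list alone; median log2 -0.31, adjusted p = 0.269), with RAD52 2.72-fold higher and EXO1 2.84-fold and MCM8 2.73-fold lower. TP53BP1 (15:43403061-43510728), which favours end joining, rose 1.86-fold to 96.8 ± 1.54 CPM from 52.1 ± 2.91 (SD, n = 3; adjusted p = 2.38e-05), and STN1 rose 3.96-fold, while LIG4 fell 4.7-fold. Their list had 5 of 20 higher and 8 lower (adjusted p = 0.709). POLQ, the end joining polymerase gene, and EZH2, a histone methyltransferase gene linked to fork stability, fell 2.04-fold and 2.1-fold (adjusted p = 0.000332 and 6.2e-06). SLFN11 fell 2.69-fold to 19.5 ± 0.980 CPM (SD, n = 3; adjusted p = 0.00357), and TP53 rose 1.56-fold (adjusted p = 0.00234). PARP1 (log2 0.03, adjusted p = 0.804) and PARG (log2 0.01, adjusted p = 0.948) were not past the threshold. The base excision list had 8 of 28 higher and 7 lower (7 and 7 adjusted over the list alone; adjusted p = 0.717), the Fanconi list 8 of 22 higher and 7 lower (adjusted p = 0.89) and the fork list 5 of 26 higher and 12 lower (adjusted p = 0.532). By fry the homologous recombination and fork lists were lower (adjusted p = 0.0087 and 0.0361) and the base excision list higher (adjusted p = 0.0087). FANCF rose 2.7-fold and FANCA fell 2.65-fold, and REV3L rose 2.06-fold. Drug efflux genes had 4 of 11 higher and 5 lower (adjusted p = 0.843), with ABCC1 2.17-fold higher, and ABCB1 had 3, 6 and 49 counts in PEO4 and was not tested. With the 2 separated libraries left out, homologous recombination had 9 higher and 19 lower, end joining 6 and 10, base excision 13 and 8, Fanconi 10 and 8, fork 9 and 14 and efflux genes 5 and 6.

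NF-kB, apoptosis, NRF2 and epithelial lists fell in PEO4, and antigen presentation rose. NF-kB targets had 14 of 24 lower and 3 higher (15 and 3 adjusted over the list alone; median log2 -1.69, or -1.54 with the floor; adjusted p = 0.00784, but adjusted p = 0.863 with an estimated correlation), with IER3 82.8-fold lower. Antigen presentation genes had 10 of 20 higher and 2 lower (median log2 0.64, adjusted p = 0.0481, but adjusted p = 0.863 with an estimated correlation), with CD74 20.7-fold higher and CD274 6.24-fold lower, and 17 higher and 2 lower without the 2 separated libraries. That list lost its call without PEO1 replicate 1 (adjusted p = 0.116) or 2 (0.104), PEO1-R replicate 2 (0.0581) or 3 (0.0534), or PEO4 replicate 1 (0.0609), 2 (0.0552) or 3 (0.0501). Apoptosis genes had 16 of 26 lower and 6 higher (17 and 6 adjusted over the list alone; median log2 -0.54, adjusted p = 0.042, but adjusted p = 0.345 with an estimated correlation), with CASP3 2.97-fold lower and CASP1 5.05-fold higher. NRF2 targets had 14 of 22 lower and 3 higher (median log2 -1.01, adjusted p = 0.0481, but adjusted p = 0.863 with an estimated correlation), with NQO1 4.32-fold lower. It lost its call without PEO1 replicate 1 (adjusted p = 0.0712) or 2 (0.0596), or PEO4 replicate 1 (0.064) or 2 (0.0552). FTH1 was 3.14-fold lower, with most of its exon bases shared with a gene on the opposite strand. Epithelial genes had 18 of 30 lower and 2 higher (median log2 -0.52, adjusted p = 0.0106, but adjusted p = 0.808 with an estimated correlation), with CDH3 8.17-fold and KRT7 4-fold lower and CDH1 1.43-fold higher. Mesenchymal genes were split, 8 higher and 12 lower of 28 (adjusted p = 0.623), with TAGLN 22.7-fold higher and TGFBI 90.6-fold lower. With the separated libraries left out, NF-kB targets had 5 higher and 19 lower, apoptosis genes 6 and 19, NRF2 targets 3 and 16, epithelial genes 6 and 23, and mesenchymal genes 7 and 15 of 30. No list called in PEO4 held its call with an estimated correlation.

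The remaining lists of PEO4 were not past the threshold against other genes. By fry, which does not compare with other genes, the stem-cell (adjusted p = 3.62e-05), receptor kinase and PI3K-MAPK signalling (0.00124), fatty acid (0.00246), hypoxia (0.00691) and unfolded protein response (0.0181) lists were lower. The oxidative phosphorylation and TGF-beta lists were higher by fry (adjusted p = 0.00465 for each). The medians of 2 of these lists went against fry: log2 0.41 for the stem-cell list and log2 -0.74 for the TGF-beta list. Their means, log2 -0.19 and 0.28, followed it. Targets of p53 had 6 of 25 higher and 10 lower (adjusted p = 0.709), with FAS 2.99-fold higher and CDKN1A 6.48-fold lower. Unfolded protein response genes had 2 of 30 higher and 12 lower (2 and 11 adjusted over the list alone; adjusted p = 0.111, but 0.0254 without PEO1-R replicate 1, 0.00264 without both separated libraries, with 5 higher and 22 lower, and 0.0177 with a term for them), with NUPR1 13.8-fold higher and HERPUD1 2.62-fold lower. Hypoxia genes had 3 of 26 higher and 12 lower (3 and 13 adjusted over the list alone; adjusted p = 0.227), with NDRG1 3.64-fold lower. Cholesterol genes had 3 of 24 higher and 14 lower (adjusted p = 0.144; 8 and 15 without the 2 libraries), fatty acid genes 6 of 22 higher and 8 lower (7 and 8 adjusted over the list alone; adjusted p = 0.843; 11 and 9 without the 2 libraries) and oxidative phosphorylation genes 14 of 39 higher and 10 lower (adjusted p = 0.593). LSS fell 2.01-fold, ACSL4 fell 3.58-fold and CYC1 rose 4.28-fold. Receptor kinase and PI3K-MAPK signalling genes had 9 of 36 higher and 16 lower (adjusted p = 0.227), with FGFR3 187-fold and PTEN 2.62-fold higher and DUSP4 97.1-fold lower. TGF-beta and BMP targets had 9 of 22 higher and 9 lower (adjusted p = 0.834), with BMP7 58.2-fold and ID4 18.4-fold higher. WNT genes had 6 of 20 higher and 7 lower (8 and 7 adjusted over the list alone; adjusted p = 0.997; 11 and 8 without the 2 libraries), with WNT11 57.3-fold higher and WNT7B 15.8-fold lower. Stem-cell genes had 7 of 17 higher and 6 lower (adjusted p = 0.965), with ALDH2 6.62-fold higher and ALDH1A3 301-fold and CD44 11.7-fold lower. With the 2 libraries left out, p53 targets had 7 higher and 13 lower, hypoxia genes 5 and 13 of 27, oxidative phosphorylation genes 19 and 15, receptor kinase and PI3K-MAPK signalling genes 12 and 23, TGF-beta targets 11 and 11 of 23 and stem-cell genes 9 and 8.

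Quality, handling and other cell type lists of PEO4 were not past the threshold with all libraries. Mitochondrially encoded mRNAs had 6 of 13 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.111, but 0.0489 with a term for the 2 separated libraries), with MT-ND6 2.96-fold higher. Histone genes had 7 of 21 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.227), and immediate early genes 0 of 16 higher and 5 lower (0 and 4 adjusted over the list alone; adjusted p = 0.269), with DUSP1 8.38-fold lower. Without the 2 libraries the immediate early list had 4 higher and 11 lower (adjusted p = 0.035), mitochondrial mRNAs 7 and 0, histone genes 8 and 3 of 22, fibroblast markers 6 and 0 of 10, mesothelial 6 and 3, endothelial 3 and 2, neuronal 2 and 1 and leukocyte markers 1 and 1. By fry the histone, mesothelial and fibroblast lists were higher (adjusted p = 8.15e-05, 0.00246 and 0.018). Fibroblast markers had 5 of 8 higher (PCOLCE 3.41-fold; adjusted p = 0.131) and mesothelial markers 5 of 9 higher and 3 lower, with WT1 8.62-fold higher (adjusted p = 0.269). Endothelial markers had 4 of 8 higher and 2 lower, with ESAM 2.92-fold higher (adjusted p = 0.709), and neuronal markers 2 of 7 higher and 1 lower, with SNAP25 7.27-fold higher (adjusted p = 0.89). Leukocyte markers had 1 of 3 higher, ITGB2, and 1 lower, CD14 (adjusted p = 0.996). Median, mean and test differed in sign, in lists with no call, for the Fanconi, stem-cell, endothelial and neuronal lists in both lines. The same held for the fork, efflux, p53 and NRF2 lists in PEO1-R and for the mesenchymal, TGF-beta and leukocyte lists in PEO4.

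Segments of neighbouring genes were compared between PEO4 and PEO1 in the same bins. Of 284 bins 47 were higher and 73 lower, and 52 held with an estimated correlation. As for PEO1-R, the list tests kept members that lie in called bins, so genes named from a list may have moved with their neighbours. The end of chromosome 8, at 140 to 150 Mb, rose most clearly, with a median log2 change of 1.89 over 105 genes (98.1% higher, adjusted p = 6.48e-25, and 0.00583 with an estimated correlation), among them the zinc transporter gene SLC39A4 (942-fold). Genes at 0 to 10 Mb of chromosome 16 (197 genes, median log2 0.80, adjusted p = 1.37e-09), of chromosome 1 (145 genes, median log2 0.82, adjusted p = 4.82e-09) and of chromosome 4 (106 genes, median log2 0.91, adjusted p = 1.74e-08) also rose, with SLC9A3R2 7.29-fold and SLC26A1 7.65-fold higher. Genes at 0 to 10 Mb of chromosome 20 fell (82 genes, median log2 -1.41, adjusted p = 1.65e-09), with SIRPA 8.34-fold and SIRPB1 136-fold lower. Genes at 140 to 150 Mb of chromosome 3 (35 genes, median log2 -1.29) and 240 to 250 Mb of chromosome 1 (41 genes, median log2 -1.16) fell as well (adjusted p = 6.8e-07), with PLOD2 4.13-fold and AKT3 10.5-fold lower. Genes at 0 to 10 Mb of chromosome 9 fell with a median log2 change of -1.27 (35 genes, adjusted p = 2.97e-06, but adjusted p = 0.0537 with an estimated correlation), with RIC1 2.63-fold lower. The bin that holds BRCA2 fell, with a median log2 change of -0.79 over 34 genes (adjusted p = 0.000318), though BRCA2 itself did not differ.

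How the 2 resistant lines differ from each other was asked by comparing PEO4 with PEO1-R, with 3 libraries each. BRCA2 was 2.48-fold lower in PEO4 than in PEO1-R (log2 -1.31, adjusted p = 9.48e-06), and BRCA1 was 2.9-fold lower (log2 -1.54). ESR1 and HOXB3 were 226-fold and 454-fold higher in PEO4, HOXB4 at least 2430-fold higher and IL1B at least 353-fold lower, a bound that rests mostly on PEO1-R replicate 1 (41.7 CPM, against 6.81 and 8.91 in replicates 2 and 3). KRT4, a keratin gene, stood at 477 ± 15.5 CPM (SD, n = 3) in PEO4, a ratio of 14000 (95% counting interval 3880 to 116000). In all, 5210 genes were higher and 5475 lower, 64.2% of those tested, with 3163 and 3189 at least 2-fold apart. The counts were 6852 and 6708 without PEO1 replicate 3 and PEO1-R replicate 1. Interferon-stimulated genes (38 of 41 higher, adjusted p = 2.02e-13), ovarian lineage genes (14 of 18 higher, adjusted p = 0.000159) and mitochondrially encoded mRNAs (13 of 13 higher, adjusted p = 0.00534) rose in PEO4 against PEO1-R, and each had adjusted p = 0.829 with an estimated correlation. Without the 2 libraries the antigen presentation and immediate early lists passed as well (adjusted p = 0.00423 and 0.00693; 16 of 20 and 14 of 16 higher). Antigen presentation also passed without PEO1-R replicate 1 alone (0.0196) and with a term for the 2 libraries (0.00471).

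Lists lower in PEO4 than in PEO1-R were the mitotic list (27 of 31 lower, adjusted p = 2.54e-06), the replication list (22 of 36 lower, 23 adjusted over the list alone, adjusted p = 0.0123), the mesenchymal list (18 of 28 lower, adjusted p = 0.0123) and NRF2 targets (14 of 22 lower, adjusted p = 0.0354). Each had adjusted p = 0.829 with an estimated correlation, and the replication list had adjusted p = 0.0572 without PEO1-R replicate 1. NF-kB targets had 18 of 24 lower (adjusted p = 0.00363, but adjusted p = 0.837 with an estimated correlation). FGFR1 and CD44 were 17.9-fold and 18.9-fold lower and CD74 142-fold higher. By segment, 49 bins were higher and 86 lower, with 0 to 10 Mb of chromosome 4 at a median log2 change of 1.84 (106 genes, adjusted p = 3.99e-19). The HOX list (15 of 22 lower, adjusted p = 0.0865) passed without PEO1-R replicate 2 (0.0434) or PEO4 replicate 1 (0.0353), 2 (0.039) or 3 (0.0267). By fry further lists were lower: checkpoint (adjusted p = 2.36e-05), apoptosis (0.000187), stem-cell (0.000484), homologous recombination (0.00141), receptor kinase and PI3K-MAPK signalling (0.00205), end joining and fatty acid (0.0108 each) and HOX (0.0393). Higher by fry were mesothelial (0.00122), TGF-beta and histone (0.00141 each), antigen presentation (0.00259), oxidative phosphorylation (0.00734) and Fanconi (0.0253). Some of these directions were not borne out by the members. The histone list had 6 higher and 5 lower (median log2 -0.066) and the Fanconi list 5 higher and 6 lower (median log2 0.013). The fatty acid list had 7 higher and 9 lower (median log2 -0.096, but mean log2 0.046). Genes expressed in PEO4 alone numbered 105 and those expressed in PEO1-R alone 33, or 51 without PEO4 replicate 3.

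Whether the 2 resistant lines changed the same genes was asked by setting the comparisons with PEO1 side by side. CLDN16, HTRA1 and the neuropilin gene NRP2 rose in both, 90.4-fold, 98.1-fold and 14.8-fold in PEO1-R and 215-fold, 268-fold and 36.3-fold in PEO4. Without PEO1 replicate 1 the log2 changes of CLDN16 were 7.11 and 8.39 and those of HTRA1 7.61 and 9.08, against 6.50 and 7.75 and against 6.62 and 8.06 with it. The sulfatase gene SULF2 rose 7.21-fold and 13.6-fold. The retinol transporter gene STRA6 fell 6.74-fold in PEO1-R and 20.2-fold in PEO4, and the guidance gene SLIT2 fell 9.68-fold and 7.54-fold. The decoy receptor gene IL1R2 fell 12.8-fold and 167-fold. ESR1, HOXB2, HOXB3 and HOXB4 went opposite ways, lower in PEO1-R and higher in PEO4.

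By count, 1438 genes moved the same way (688 higher, 750 lower) and 1220 opposite ways. Independent lists of these sizes would share 568 higher and 646 lower genes, and 600 and 612 in the opposite directions. Of the genes called in PEO1-R, 35.8% were called the same way in PEO4 and 30.4% the opposite way. Both comparisons use the same 3 PEO1 libraries, which cannot be split, so part of the excess may come from shared controls. Simulated groups with no change gave a correlation of log2 changes of 0.479 from the shared controls alone, against 0.0989 observed, and a covariance of 0.0718 against 0.176, a difference of 0.104. Those simulations had at most 1 gene called in both, which follows from having no change to call, so they give no measure for the overlap counts. They also drew each library independently, without the shared deviations of PEO1 replicate 3 and PEO1-R replicate 1. Without PEO1 replicate 3 and PEO1-R replicate 1 the counts were 4513 and 3568, where independent lists would share 3849 and 3849. Without PEO1-R replicate 1 alone they were 2360 and 2051, and without PEO1 replicate 3 alone 2263 moved the same way. They were 831 and 740 without PEO1 replicate 1, 859 and 720 without PEO1 replicate 2, 908 and 727 without PEO1-R replicate 2, and 951 and 792 without PEO1-R replicate 3.

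**Figure D5:**
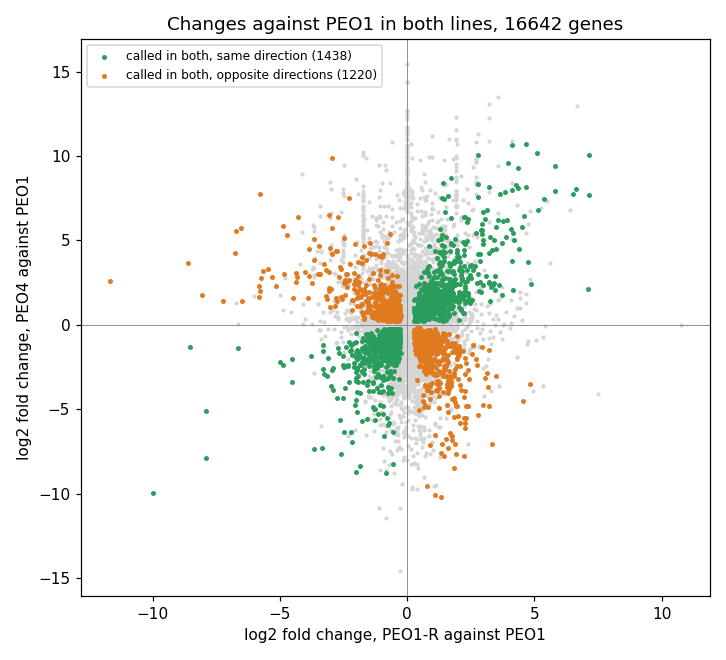
Log2 fold change in PEO1-R against PEO1 (x axis) and in PEO4 against PEO1 (y axis) for 16642 genes. Green genes (1438) moved the same way in both and orange genes (1220) opposite ways.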

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

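The test of PEO1 RNA by genes silent in PEO1-R, the test of swapped labels and the test of a shared batch were chosen after the pattern they address was seen.

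PEO1 replicate 3 and PEO1-R replicate 1 lay apart from the other libraries of their lines, and this might reflect mixed cells, swapped labels or a shared culture or library batch. A share of PEO1-R RNA in PEO1 replicate 3 was not seen. Genes higher in PEO1-R lay at -0.00215 of the way towards it (95% interval -0.0167 to 0.0255). Genes lower in PEO1-R lay at -0.249, that is, away from it. Such positions also move with other differences of a library, as PEO1-R replicate 1 shows next. A small share is therefore not excluded. In PEO1-R replicate 1 genes of both classes lay at least 0.231 of the way towards PEO1, but such a share of PEO1 RNA was excluded, since 4 genes silent in PEO1-R replicates 2 and 3 had 1 count there against 166 at that share (upper 95% bound on the share 0.00774). Swapped labels were excluded, since each library correlated better with the rest of its own line than with the unseparated libraries of the other, by at least 0.0132. With each other the 2 libraries correlated at 0.967. A shared batch stays open, since the deviations of the 2 libraries correlated at 0.73 over 4412 genes level between the other 4 libraries.

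Neighbouring genes differed together between PEO1-R and PEO1 in 66 bins, against at most 1 bin in 100 shuffles, so a chance arrangement of genes was excluded. Of these bins 53 held without genes that changed more than 2-fold, which excluded a few strong clusters, and 52 held without PEO1 replicate 3 and PEO1-R replicate 1, which excluded the 2 libraries as the source. Between PEO4 and PEO1 there were 120 such bins against at most 1 in shuffles, and 62 held without the strongly changed genes. A dosage shift of whole segments, such as a DNA copy number difference, was left untested, and no DNA data were used here. The share of genes on the bin's side, a median over called bins of 78.1% in PEO1-R and 77.3% in PEO4 against 58.8% and 60.5% over the other bins, does not decide it, since the bins were chosen for a shift to a side.

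For each pair of lines the other 9 of the 10 ways to split its 6 libraries into 3 and 3 gave at most 0 genes past the threshold. The real splits gave 2168 for PEO1-R against PEO1, 10451 for PEO4 against PEO1 and 10833 for PEO4 against PEO1-R, and the count of splits as high as the real one was 1, 1 and 1. These splits are too few for a share under 0.05.

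The library totals behind the FPKM exceeded the summed counts by 4.80%, 11.5% and 11.9% in PEO1-R replicates 1, 2 and 3, more than in PEO1 or PEO4, and what the further counts were is not known. Genes called in opposite directions in PEO1-R and PEO4 against PEO1, and different between these lines by test, numbered 1220.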

How the results depend on the processing

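The settings without PEO1 replicate 3 and PEO1-R replicate 1, with a term for these 2 libraries and with the totals behind the FPKM were chosen after the results were seen. Limits apply to all results: 3 libraries per line, which the labels do not give as separate cultures, a single resistant line of each kind, RNA from bulk culture, and replicates of unequal spread. Of the count results 238 were the same and 72 moved, none reversed. For gene lists 1444 were the same, 60 stronger, 50 weaker and 66 changed sign with no call in either setting. For named genes these were 13047, 23, 387 and 35. The cause of each shift was not tested unless said.

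PEO1-R against PEO1, with 1932 higher and 2081 lower, gave 1081 and 1087 with its 6 libraries alone. The same setting lowered neither PEO4 against PEO1 (5213 and 5238) nor PEO4 against PEO1-R (5319 and 5514). Those comparisons keep the close PEO4 replicates and leave out a more spread line. They therefore cannot tell what fewer libraries alone do. The main fit also draws its spread from PEO4, whose replicates correlated at 0.991 to 0.992, against as low as 0.974 in PEO1 and 0.968 in PEO1-R. For PEO1-R against PEO1 an adjusted p of 0.01 gave 884 and 991, and a test against 1.5-fold 495 and 397, by construction fewer. Without the 2 separated libraries there were 4860 and 4961, and with a term for them 3919 and 4040. Leaving out 1 library gave 1146 to 2815 higher and 1261 to 3274 lower.

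PEO4 against PEO1, with 4895 and 5168, gave 2974 and 2966 in the test against 1.5-fold, and 4274 to 5624 and 4481 to 5776 on leaving out 1 library. PEO4 against PEO1-R, with 5210 and 5475, gave 3318 and 3406, and 4650 to 5851 and 4820 to 5856.

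Genes moved the same way (1438) and opposite ways (1220) in PEO1-R and PEO4 numbered 793 and 680 with 6 libraries per contrast, 580 and 485 at an adjusted p of 0.01, and 269 and 209 against 1.5-fold. They numbered 4513 and 3568 without the 2 libraries, 3228 and 2880 with the term, and 831 to 2360 and 720 to 2051 on leaving out 1 library.

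Bins of 20 Mb, which are fewer, gave 15 higher and 22 lower in PEO1-R against PEO1 (32 and 34 at 10 Mb), 29 higher in PEO4 against PEO1 (47), and 31 higher and 55 lower in PEO4 against PEO1-R (49 and 86). With an estimated correlation these were 9 and 18 for PEO1-R against PEO1, 23 and 29 for PEO4 against PEO1 (47 and 73), and 29 and 32 for PEO4 against PEO1-R.

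Genes expressed in a single line depended on the minimum. With 1 CPM in place of 5 there were 10 in PEO1-R and 9 in PEO1, 278 in PEO4 and 78 in PEO1, and 299 in PEO4 and 113 in PEO1-R. With 0 counts in place of 3 in the silent line there were 2 in PEO1 against PEO1-R, 48 in PEO4 and 4 in PEO1, and 54 in PEO4 and 12 in PEO1-R. Without the 2 libraries there were 2 in PEO1-R against PEO1. Leaving out 1 library gave 1 to 3 in PEO1-R and 4 to 5 in PEO1, 92 to 118 in PEO4 and 18 to 32 in PEO1, and 103 to 133 in PEO4 and 31 to 51 in PEO1-R.

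The replicate number as a block gave 1326 and 1474 genes in PEO1-R against PEO1 and 981 shared and 810 opposite genes. It moved the antigen presentation, NRF2 and apoptosis lists of PEO4 to adjusted p = 0.0564, 0.0544 and 0.0544. The pairing check gave correlations of -0.468, 0.282 and -0.437 between same-numbered PEO1 and PEO1-R libraries, so the numbers do not pair them.

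By setting, calls of named genes were weaker for 88 in the test against 1.5-fold, 45 at an adjusted p of 0.01, 26 with 6 libraries, 18 without the low-count filter, 18 with the block and 10 with library size scaling. Leaving out a library made them weaker for 26, 22 and 7 (PEO1 replicates 1, 2 and 3), 6, 24 and 19 (PEO1-R) and 17, 20 and 21 (PEO4). The estimated correlation made 24 gene lists weaker, and fry made 31 stronger and 2 weaker.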

Other observations

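The analysis of the 2-library term below was chosen after the separation of PEO1 replicate 3 and PEO1-R replicate 1 was seen.

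PEO1 replicate 3 and PEO1-R replicate 1 differed together from the other libraries of their lines, and whether by biology or by batch was not separated. Cholesterol synthesis genes stood higher in these 2 libraries, 17 of 24 with 0 lower (median log2 0.82, camera adjusted p = 3.35e-08, but adjusted p = 0.156 with an estimated correlation), as did antigen presentation genes (14 of 20 with 0 lower, adjusted p = 1.27e-06, but 0.162 with an estimated correlation). Interferon-stimulated genes (20 of 41 with 1 lower, adjusted p = 0.00028, but 0.0882) and WNT genes (13 of 20 with 0 lower, adjusted p = 0.00013, but 0.0882) were higher too. Unfolded protein response genes were lower (16 of 30 with 4 higher, adjusted p = 0.000483, but 0.162), as were NRF2 targets (10 of 22 with 2 higher, adjusted p = 0.00167, but 0.232). Immediate early genes, a sign of handling, were higher (12 of 16 with 1 lower, median log2 1.27, adjusted p = 0.00275, but 0.653), and so were NF-kB targets (9 of 24 with 1 lower, adjusted p = 0.00468, but 0.633). Ovarian lineage genes (5 of 18 with 1 lower, adjusted p = 0.0305, but 0.608) and leukocyte markers (3 of 3, adjusted p = 0.0402, but 0.259) were higher as well. In all, 6847 genes differed with this term, 3488 higher and 3359 lower, against 3919 higher and 4040 lower between PEO1-R and PEO1 in the same fit.

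Deviations of the 2 libraries, which correlated at 0.73, may come from cell density, medium age, handling or harvest day at culture, or from library preparation. Growing both lines side by side at set densities, with harvest days recorded, would test it. If the deviations follow density, the cholesterol and interferon lists would shift with density in both lines alike.

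The rise of BRCA2 mRNA in PEO1-R might reflect a transcript freed from decay, a changed allele or a stronger promoter. The change was log2 1.22 with all libraries, and its genomic bin was not past the threshold, while 66 bins elsewhere were. Sequencing of the BRCA2 transcript and a blot of its protein in PEO1-R and PEO1, with a RAD51 focus assay after irradiation, would separate these. RNA levels alone do not show whether the protein works.

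The shift of neighbouring genes, in 66 bins of PEO1-R and 120 of PEO4, may reflect DNA copy number or another cause that acts on whole regions, and neither was tested. Low-coverage DNA sequencing of the 3 lines would test this for chromosome 4, where genes at 0 to 20 Mb fell and genes at 30 to 50 Mb rose in PEO1-R. If copy number explains it, DNA depth would step at the same places.

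The 2 resistant lines might have reached resistance by different states, which these data do not test. The number of genes that moved in opposite directions, 1220, does not speak for it, since independent lists of these sizes would share 600 and 612. Without the 2 separated libraries it was 3568, against 3849 for independent lists of those sizes. OVOL1 fell and ZEB2 and VIM rose in PEO1-R, while interferon-stimulated genes rose in PEO4 (adjusted p = 0.345 with an estimated correlation). The epithelial list fell in both lines, with 17 of 30 lower in PEO1-R (median log2 -0.60) and 18 of 30 in PEO4 (median log2 -0.52), and 2 higher in each. Restoring OVOL1 or silencing ZEB2 in PEO1-R, and blocking JAK signalling in PEO4, each followed by an olaparib dose curve, would show whether either state bears on resistance. SLFN11 is a further candidate, at log2 -0.65 in PEO1-R with all libraries and log2 -1.07 without the 2 separated ones. Its protein level and a knockdown in PEO1 would test it.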
